A study of Mus musculus and Acomys cahirinus with 2 samples.

How the data were processed

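Adult ear skin of Mus musculus and of Acomys cahirinus was measured by droplet single-cell RNA sequencing, with 1 library per species and both labelled day 0. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 2.2.0, per the submitters' processing notes, which name the genome build mm10 for both libraries. The Mus gene list pairs mouse Ensembl identifiers with symbols, whereas the Acomys gene list holds mouse-like symbols and 8324 names that are identifiers alone, so it follows an Acomys annotation, whose build is not given in the sources used here. Both matrices hold all 737280 barcodes with no cell filter. The Mus list held 28692 genes, 13 of them mitochondrial, and the Acomys list 24509 genes, none of them mitochondrial. Some naming markers, such as Krt14 and Krt6a, had no symbol in the Acomys list, and a symbol in both lists need not mark the same gene where gene families differ between the species.

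Cells were barcodes with at least 1/10 of the UMI total at the 99th percentile of the 3000 largest barcodes and at least 200 genes, which set the UMI minimum at 4695 in Mus and 2871 in Acomys. Mus cells with over 20% of UMIs on mitochondrial genes (4 cells) were left out. Doublets were scored with an implementation of the Scrublet method, and the highest-scoring cells were left out at 0.8% per 1000 cells (386 Mus and 183 Acomys cells). Cells held 68.8% of the UMIs of the Mus library and 55.3% of those of the Acomys library. Each library was clustered by itself: counts were scaled to 10000 per cell and taken as natural log of 1 plus the value, 2000 variable genes and 30 principal components were kept, and cells were grouped by the Leiden method at resolution 1 on the graph of 20 nearest neighbours with seed 1. This gave 18 clusters in Mus and 21 in Acomys.

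A cluster was named X-like from fixed marker genes of 23 types. A marker counted where at least 20% of the cells of the cluster had a UMI and its geometric mean level was at least 1.5 times the mean of the other clusters, and a name needed at least 3 counted markers. A cluster stayed unnamed where its 10 leading genes held more markers of another type, or where its median UMI total was under 1/3 of its library with no marker of the type among its leading genes. The markers were fixed before the data were examined, as were the gene lists, the rule for named genes, the measures and the alternatives not said to be added. The scoring of markers and the percentiles that decide which lists are described were chosen after the data were examined. So were the 6 marker types described in full over whole libraries and the ratios between classes of the same library.

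UMI counts were summed per class and library. The ratio of Acomys to Mus CPM over the 15688 shared symbols was given with an exact conditional binomial 95% interval. Log2 ratios used a prior count of 0.5. Against a library without a UMI of the gene in the class, the ratio is a lower bound from 3 counts in that class. The named genes of a class with at least 100 cells in both libraries had at least 10 UMIs in all cells of each library, and at least 30 CPM and 20 UMIs in the class of the higher library. From these, the 12 with the highest and the 12 with the lowest ratio, by the interval bound nearest to 1, were named in the 3 largest classes, and 5 and 5 in the others. The rule left out ribosomal, mitochondrial, histone, MHC, immunoglobulin and T cell receptor genes, the Krtap, Lce and Sprr families and names that are identifiers alone. From a described list, up to 4 members of highest level and members with a ratio of at least 4 or at most 0.25 whose interval excluded 2 or 0.5 were eligible for naming. Apart from that rule, genes named in the whole-library sums, the cell cycle shares, the clusters and the ratios between classes were chosen after their values were seen.

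The median log2 ratio of a list with at least 5 members at 10 CPM or more was set against 10000 random lists of as many genes, matched in 20 expression bins, and described at or below percentile 2.5 or at or above 97.5. Of 32 fixed lists, those too thinly measured in a class were left out of it. The same ratio in all other cells of both libraries was computed for each gene, so that a ratio shared by every class can be seen. Shares of cells carry exact Clopper-Pearson intervals. Endothelium-like and chondrocyte-like cells, too few among the main cells, were compared with a minimum of 1000 UMIs.

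Alternatives were UMI minimums of 500 and 1000, a mitochondrial limit of 10% or none, no doublet removal, resolutions 0.5 and 2, 15 components, and joint clustering on 1740 genes. Gene ratios and lists were also centred on genes of at least 50 CPM, scaled without ribosomal proteins, corrected for 10% free RNA with the profile of barcodes of 1 to 10 UMIs, averaged over cells, taken relative to the other cells, or restricted to other list members. Added alternatives counted unnamed clusters in the type with most counted markers, left out cycling clusters (at least 5 cell cycle markers) or left out naming markers. The ratio step was tested on simulated counts with 200 genes given known ratios. It recovered 100% of 2-fold, 4-fold and 16-fold genes among 6636 in basal and 5824 in suprabasal cells. At 2-fold it recovered 85.9% among 6682 in follicle and 87.3% among 6473 in sebocyte-like cells, with 100% there at 4-fold and 16-fold. A gene counted as recovered where its interval excluded 1 on the right side. Both libraries were drawn from 1 averaged profile, so the simulation holds no difference in annotation or capture. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.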

Results

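Single cells of adult ear skin were profiled with the 10x Genomics Chromium 3' assay in Mus musculus, the house mouse, and in Acomys cahirinus, a spiny mouse known for regrowing ear tissue after injury. Each species has 1 library, labelled day 0, and the series text describes the ears as injured. The comparison asks how the cells of the ear differ between the species at that time. With 1 library per species there are no replicates, so no test was made, and each difference joins species, animal, library and reference annotation. The Mus library held 130039670 UMIs (unique molecular identifiers, which mark captured transcripts) and gave 6556 cells with a median of 11734.5 UMIs and 2768 genes. The Acomys library held 71042559 UMIs and gave 4603 cells with a median of 7500 UMIs and 1907 genes. The lowest UMI total kept was 4695 in Mus and 2875 in Acomys. Gene values are CPM, UMI counts scaled to a fixed total per class, over the 15688 genes with a symbol in both gene lists, which held 62.1% of the UMIs of Mus cells and 66.8% of those of Acomys cells. Intervals in parentheses are exact 95% intervals and cover counting error only.

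Keratinocytes, hair follicle cells and sebocytes formed the large named classes of both libraries, named by marker genes. Basal keratinocyte-like cells, which resemble the dividing layer of the epidermis, made up 51.8% of Mus cells (50.6 to 53.02) and 19.7% of Acomys cells (18.6 to 20.9). Suprabasal keratinocyte-like cells, which resemble the differentiating layers, made up 24.8% (23.8 to 25.9) and 21.1% (19.9 to 22.3). Hair follicle and appendage-like cells made up 5.58% (5.04 to 6.17) and 14.6% (13.6 to 15.7). Sebocyte-like cells, the lipid-making cells of the sebaceous gland, made up 4.13% (3.66 to 4.64) and 7.13% (6.40 to 7.91). Blood endothelium-like cells numbered 43 in Mus and 84 in Acomys. A fibroblast-like cluster of 52 cells was named in Mus, and chondrocyte-like (32 cells), T cell-like (29) and melanocyte-like (19) clusters were named in Acomys. These calls depended on the settings. A minimum of 1000 UMIs gave 55 Mus and 175 Acomys chondrocyte-like cells. Clustering the libraries together gave 34 and 53 fibroblast-like and 16 and 28 T cell-like cells. The joint clusters of the large named classes, however, split by library, such as basal clusters of 2044 Mus and 13 Acomys cells and of 2 and 653. The joint blood endothelium-like cluster held 43 Mus and 0 Acomys cells. Unnamed clusters held 12.2% of Mus cells and 33.9% of Acomys cells, and clusters with at least 5 cell cycle markers held 8.74% and 7.93%. The unnamed clusters included 717 Acomys cells with basal markers, led by Fst and Cyp1a1, and 247 such Mus cells, led by mitotic genes such as Cenpa and Cdc20. A further 140 unnamed Acomys cells held suprabasal markers and were led by Klk5 and S100a8. The shares stand side by side with no order read from them. Summed over all cells of each library, the naming markers differed at least 2-fold for 3 of 7 basal, 2 of 6 suprabasal, 9 of 10 follicle and 8 of 8 sebocyte markers with a shared symbol. These sums also move with the class shares, so they do not show by themselves that markers were captured differently. The minimum UMI total differed too. With a minimum of 500 UMIs in both libraries the basal share was 9.48% in Mus and 14.7% in Acomys, the opposite order. With the unnamed basal-marker clusters counted in, the basal share was 55.6% and 35.3% among the main cells. It was 34.3% and 23.4% with them counted in at the minimum of 500 UMIs.

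**Figure D1:**
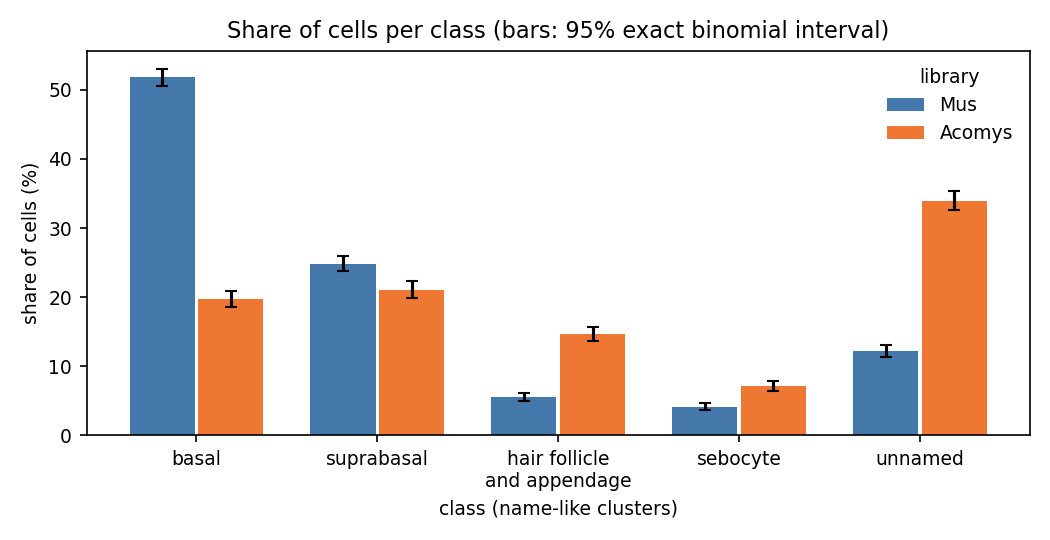
Share of cells (percent) per named class and in unnamed clusters, for the Mus and the Acomys library, with bars for exact 95% binomial intervals of counting error. The basal share was 51.8% in Mus and 19.7% in Acomys, and the unnamed share was 12.2% and 33.9%.

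Marker genes of cell types summed over all cells of each library gave levels for types with few cells. The 6 types described in full were chosen after the data were examined. Among the others, the largest differences were Schwann cell markers, 101-fold lower in Acomys, and neutrophil and adipocyte markers, 14.6-fold and 5.64-fold higher. At least 2-fold higher and lower were 1 and 5 of 9 Schwann cell, 3 and 2 of 6 neutrophil, and 5 and 0 of 7 adipocyte markers. For 3 of the 9 Schwann cell markers 1 library had no UMI, and the median log2 ratio of these markers was -1.86. Over all barcodes Schwann cell markers were 68.0-fold lower, and neutrophil and adipocyte markers 3.58-fold and 5.11-fold higher. S100a8, a neutrophil marker, also led unnamed Acomys cells with suprabasal markers, so these sums are not read as numbers of cells. Melanocyte markers were 7.36-fold higher in Acomys (6.54 to 8.31), with 5 of 8 at least 2-fold higher and 1 at least 2-fold lower, among the higher Pmel at 19.9 against 0.810 CPM and Mlana at 16.8 against 0.342 CPM. Fibroblast markers were 1.75-fold higher in Acomys as a sum (1.71 to 1.80), yet 7 of 12 were at least 2-fold lower and 3 at least 2-fold higher. Dcn, a small proteoglycan, stood at 153 against 80.6 CPM and Mgp, an inhibitor of calcification, at 155 against 17.2 CPM, whereas the fibrillar collagens Col1a1 (5.79 against 26.8 CPM) and Col3a1 (6.78 against 38.5 CPM) were lower. Dcn was also at 189 CPM in Acomys and 24.3 CPM in Mus basal keratinocyte-like cells, so its sum is not a level of fibroblasts alone. Chondrocyte markers summed to 1.26-fold higher (1.20 to 1.32), with 6 of 11 at least 2-fold higher and none at least 2-fold lower; Cytl1, at 67.7 against 71.4 CPM, held most of the sum. Blood endothelium markers were 1.19-fold higher (1.12 to 1.26), with 3 of 10 at least 2-fold higher and 2 at least 2-fold lower. T cell markers summed to 1.65-fold lower in Acomys (1.56 to 1.75), yet 5 of 12 were at least 2-fold higher and 3 at least 2-fold lower. Thy1 stood at 19.2 against 78.4 CPM, while the receptor complex genes Cd3d (11.0 against 1.64 CPM) and Cd3e (8.61 against 1.40 CPM) were higher. Macrophage markers summed to a ratio of 1.14 (0.997 to 1.30), with 2 of 11 at least 2-fold higher and 5 at least 2-fold lower, among them Cd68 at 1.30 against 3.92 CPM; over all barcodes the ratio was 1.38 (1.32 to 1.44).

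Over all genes, the ratio between the libraries in a class mostly repeated the ratio elsewhere. Across genes, the log2 ratio in basal cells correlated with the ratio in all other cells at r = 0.945, and at 0.910 in suprabasal, 0.915 in follicle and 0.888 in sebocyte cells; genes are not independent replicates. The median gene differed 2.02-fold in either direction between the libraries in basal cells, but 1.21-fold relative to its ratio in all other cells. In each of the 4 epithelial classes the same 39 genes differed over 50-fold, among genes of at least 30 CPM in each class of the higher library. Of these, 5 were higher in Acomys (Atp6v0c, Cyp1a1, Krt25, Mrpl53 and Scamp4) and 34 in Mus. The 34 include Arf1, a regulator of vesicle traffic, Jund, a subunit of the AP-1 transcription factor, Cebpa, Emp1, Tonsl, Glrx, Oxct1 and Mmp3. A ratio of this kind also holds how each gene was captured and annotated in its own reference. Genes whose ratio in a class lay at least 4-fold from their ratio in all other cells are therefore named separately for each class. That limit was taken on the ratios without their intervals. A gene with few UMIs in a class can thus pass it by counting error. All other cells pool the other classes, so a gene past the limit in a class can differ as much in another class.

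**Figure D2:**
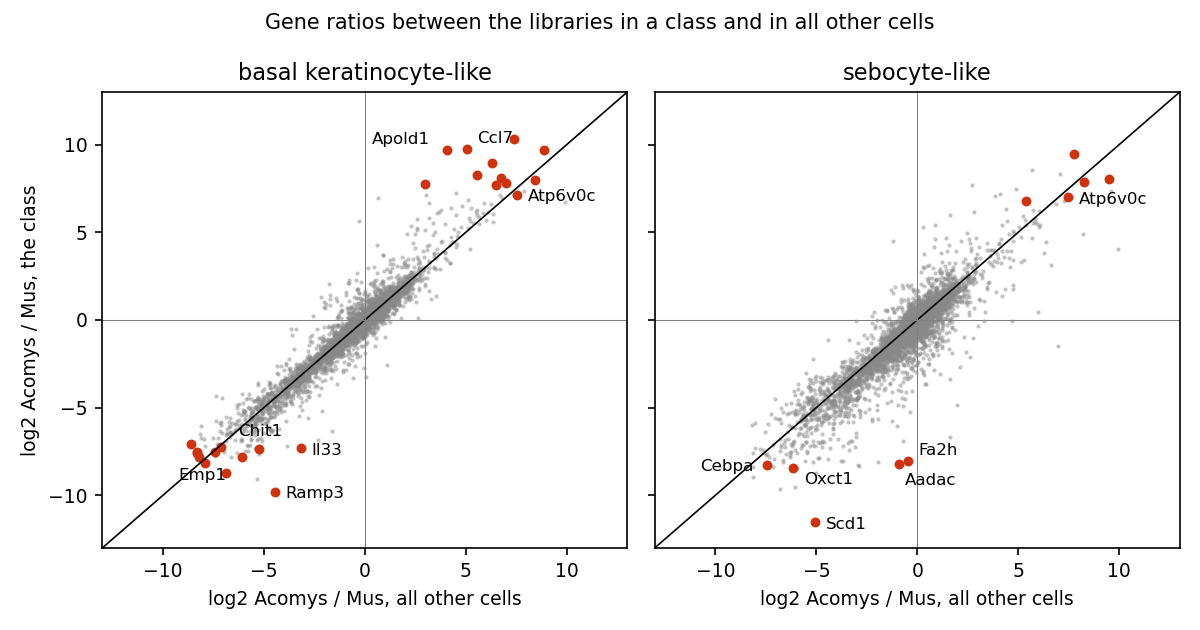
Log2 ratio of Acomys to Mus CPM per gene in all other cells (x axis) and in the class (y axis), for basal and sebocyte-like cells, with grey points for genes at 30 CPM or more in the higher library, red points for the genes named by the fixed rule and a line of equal ratios. Atp6v0c lies near the line, whereas Apold1, Il33, Aadac and Scd1 lie at least 4-fold from it.

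In basal keratinocyte-like cells (3396 in Mus, 907 in Acomys), St3gal5, the synthase of the ganglioside GM3, was higher in Acomys by 1439-fold (561 to 5289.7) against 166-fold in all other cells. The Mus class held 4 UMIs of St3gal5, and its Acomys level was 231 CPM in basal and 187 CPM in all other cells. It was also 1227-fold higher in suprabasal cells, so its ratio is not particular to basal cells. Apold1 was at 82.3 CPM in Acomys and 0.0803 CPM in Mus, a ratio of 1024 (282 to 8484) against 16.8 in all other cells. Cmbl was 542-fold higher (248 to 1483) and Snrpn, a protein of small nuclear ribonucleoproteins, 312-fold higher (194 to 537), against 78.1-fold and 46.8-fold elsewhere. Snrpn was also 514-fold higher in suprabasal cells, and within Acomys it was lower in basal cells (213 CPM) than in all other cells (272 CPM). Chit1, a chitinase, was 169-fold lower in Acomys (92.1 to 353) against 37.7-fold lower elsewhere. Within 4-fold of their ratio in other cells, Cyp1a1, Mrpl53, Sfxn4, Atp6v0c, Bdh2 and Zpbp2 were higher in Acomys. Brk1, Mtpn, Jund, Emp1, Arf1, Elof1, Carhsp1 and Smim10l1 were lower in Acomys within that limit. Ccl7 and Rasd1, named as higher, and Ramp3, Il33 and Mmp3, named as lower, were leading genes of basal clusters of a library and are not read as results. The basal cells lay in 5 clusters in Mus, 1 of them cycling, and in 4 in Acomys, 2 of them cycling.

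Of 18 gene lists compared in basal cells, 3 lay outside the middle 95% of random lists matched on expression. The interferon response list had a median log2 ratio of 1.69 (percentile 99.94), with 4 of 7 members at least 2-fold higher in Acomys and 1 lower. Ifitm2, a membrane protein against viral entry, was 3.54-fold higher (3.47 to 3.61) and Bst2, which tethers viruses, 5.24-fold higher (3.92 to 7.02). The chemokine list had a median of 3.23 (percentile 99.99), with 4 of 5 members at least 2-fold higher and none lower. Ccl2, an attractant of monocytes, was at 22.3 against 0.0803 CPM, and Cxcl16 was 2.35-fold higher (2.15 to 2.57). Of these lists, Ccl7, Ccl20, Cxcl14 and Ifitm3 led basal clusters of a library. The epidermal barrier list had a median of 0.59 (percentile 98.18) and a mean of -0.10, with 5 of 13 members at least 2-fold higher and 3 lower. Krt1 was 2.37-fold higher (2.30 to 2.44), whereas Lor, the main protein of the cornified envelope, was 6.82-fold lower (6.18 to 7.54) and Tgm3, a transglutaminase, 64.2-fold lower (31.1 to 159.8). Relative to the ratio in all other cells, the medians were 0.19 (percentile 88.2) for interferon and 0.065 (64.2) for chemokine genes, inside the random lists, and 0.30 (98.8) for barrier genes. The barrier median also lay inside them with the unnamed clusters of basal markers counted in (0.43, percentile 95.5) and without cycling clusters (0.54, percentile 97.4). With the unnamed clusters counted in, the relative medians of all 3 lists lay outside the random lists, at 0.41 (98.8) for interferon, 0.50 (99.3) for chemokine and 0.32 (99.3) for barrier genes. Without cycling clusters the relative chemokine median did too, at 0.38 (97.6), and those of interferon, 0.14 (81.2), and barrier genes, 0.12 (82.1), did not. With every member of at least 1 UMI counted, the interferon median was -0.45 and the chemokine median 1.61, without cycling clusters the interferon median was 0.95, and subtracting free RNA moved the barrier median to 0.91.

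In suprabasal keratinocyte-like cells (1629 in Mus, 970 in Acomys), Alox12e, an epidermal lipoxygenase, was 307-fold lower in Acomys (149 to 764) against 2.17-fold lower in all other cells. Tonsl, with 1 UMI in the Acomys class, was 1563-fold lower (280.4 to 61748) against 145-fold elsewhere. Glrx, a glutaredoxin with 3 UMIs in the Acomys class, was 562-fold lower (192 to 2728) against 86.3-fold. Mpeg1, a pore-forming protein, was at 53.7 CPM in Acomys against 1 UMI in Mus, a ratio of 1084 (194 to 42929) against 70.2 elsewhere. Pcsk1n had no UMI in the Mus class and was at least 220.1-fold higher in Acomys, against 46.5-fold elsewhere. St3gal5, Snrpn, Lurap1l and P4htm were also higher by at least 4 times their ratio in other cells. Mmp3, a stromelysin without a UMI in the Acomys class, was at least 313-fold lower, against 280.3-fold elsewhere. Tonsl, Glrx and Mmp3 were over 50-fold lower in Acomys in every epithelial class, so their lower level is not particular to suprabasal cells. Nearer to their ratio in other cells, Mrpl53, Atp6v0c, Cyp1a1, St6galnac2, Cmbl and Gpx2 were higher and Sptssa, Brk1, Cebpa and Emp1 lower. Npl, Wfdc21, Tesc and Dkkl1 were named as lower, but they led Mus suprabasal clusters and are not read as results. The class lay in 4 Mus and 3 Acomys clusters.

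Of 17 lists compared in suprabasal cells, 4 lay outside the random lists. Epidermal barrier genes had a median log2 ratio of -1.18 (percentile 0.31), with 8 of 14 members at least 2-fold lower in Acomys and 1 higher. Klk7, a protease of corneocyte shedding, was 4.10-fold lower (3.83 to 4.40), Casp14, a caspase of cornification, 4.35-fold (3.59 to 5.32) and Tgm3 28.8-fold (17.7 to 50.5). The naming markers Lor, Krt1, Krt10 and Krtdap are members of this list, whose median without the naming markers was -1.49. Matrix proteases and their inhibitors had a median of -2.98 (percentile 0.87), with 4 of 6 members at least 2-fold lower and none higher. Mmp2, a gelatinase, was 12.4-fold lower (10.1 to 15.5), Adamts1 20.8-fold (10.0 to 52.1) and Timp3, an inhibitor, 5.15-fold (3.34 to 8.36). The chemokine list had a median of 2.26 (percentile 99.97), with 4 of 7 members at least 2-fold higher and 1 lower. Ccl20 was 7.48-fold higher (6.48 to 8.65) and Cx3cl1 4.81-fold (3.62 to 6.44), while Ccl6 was 31.8-fold lower (10.7 to 155). Ccl2 had no UMI in the Mus class and was at least 83.8-fold higher in Acomys. The interferon response list had a median of 1.54 (percentile 99.95), with 4 of 6 members at least 2-fold higher and 1 lower. Ifitm3 was 20.9-fold higher (19.9 to 21.9), Ifitm2 4.26-fold (4.13 to 4.38) and Psmb9, a subunit of the immunoproteasome, 2.57-fold (2.33 to 2.83), and Irf9 was 5.54-fold lower (3.82 to 8.31). With the unnamed Acomys cluster of suprabasal markers counted in, the barrier median was 0.62 (percentile 99.1), outside the random lists on the opposite side. Klk7 was then higher by 0.62 on the log2 scale, as it was, by 0.74, with a minimum of 1000 UMIs. With that cluster counted in, the protease median was -2.32 (percentile 5.21), inside the random lists. Relative to all other cells the medians were -2.60 (percentile 0) for barrier and 0.56 (99.6) for interferon genes, and, inside the random lists, -0.45 (4.78) for proteases and 0.35 (90.4) for chemokines. With the unnamed cluster counted in, the relative medians of all 4 lists lay inside the random lists, at -0.26 (6.26) for barrier, 0.28 (96.5) for interferon, -0.46 (5.44) for protease and -0.077 (51.9) for chemokine genes. With members of at least 1 UMI the protease median was 0.18 and the interferon median 0.66.

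In hair follicle and appendage-like cells (366 in Mus, 672 in Acomys), Krt27, a keratin of the inner root sheath, was 123-fold higher in Acomys (80.4 to 199) against 6.49-fold in all other cells. A4galt, a glycolipid galactosyltransferase, was at 144 CPM in Acomys against 1 UMI in Mus, a ratio of 291 (52.0 to 11526) against 32.3 elsewhere. Tonsl, without a UMI in the class in Acomys, was at least 199-fold lower, against 179.8-fold elsewhere. Tonsl was over 50-fold lower in every epithelial class, so its lower level is not particular to follicle cells. Krt25 and Krt71, which are naming markers, and Krt75, Krt42, Cyp1a1, Cyp2f2 and Cyp2a5, which led Acomys follicle clusters, were named as higher and are not read as results. The Mus class lay in a cluster led by Defb6 and Krt79 and another led by Lhx2 and Lgr5. The Acomys class lay in clusters led by Krt79 and Cyp2a5, by Prss22 and Krt42, and by Krt75 and Krt35, so clusters with other leading genes make up the class in each library. Ratios in this class, that of Krt27 among them, can also hold this unlike makeup, which was not tested. Within 4-fold of their ratio elsewhere, Atp6v0c, Mrpl53 and St3gal5 were higher and Jund, Brk1, Arf1, Cebpa, Emp1, Smco4, Cdc42se1, Eef1d, Elof1, Ormdl3 and Nbl1 lower. Of 21 lists compared, 2 lay outside the random lists. Matrix proteases and inhibitors had a median of -2.33 (percentile 0.81), with 5 of 8 members at least 2-fold lower and 1 higher. Mmp2 was 29.5-fold lower (16.1 to 59.9), Timp2, an inhibitor, 5.95-fold (4.54 to 7.88) and Timp3 4.26-fold (3.34 to 5.47). Chemokines had a median of 1.07 (percentile 99.21), with 4 of 6 members at least 2-fold higher and 2 lower. Ccl20 was 36.8-fold higher (26.6 to 52.4) and Cxcl16 2.16-fold (1.87 to 2.51), while Cxcl14 was 7.91-fold lower (6.23 to 10.1). Cxcl12, without a UMI in Acomys, was at least 38.9-fold lower. Relative to all other cells the chemokine median was -0.64 (percentile 1.08), the opposite sign, and the protease median -0.18 (percentile 12.6), inside the random lists. Subtracting free RNA took the chemokine median to 0.16, and counting every member with at least 1 UMI took the protease median to 0.56.

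In sebocyte-like cells (271 in Mus, 328 in Acomys), Aadac, a lipid-hydrolysing deacetylase, was 373-fold lower in Acomys (103 to 3085) against 1.88-fold lower in all other cells. Oxct1, an enzyme of ketone body use with 2 UMIs in the Acomys class, was 431-fold lower (119 to 3564) against 70.8-fold elsewhere. Oxct1 was over 50-fold lower in every epithelial class, so its lower level is not particular to sebocyte-like cells. The lipid metabolism list had a median log2 ratio of -0.64 (percentile 2.03), with 8 of 18 members at least 2-fold lower and 3 higher. Lpl, a lipoprotein lipase, was 487-fold lower (87.0 to 19250.4), Cd36, a fatty acid transporter, 129.8-fold (35.7 to 1076), and Hmgcs1, an enzyme of cholesterol synthesis, 59.5-fold (41.3 to 89.0). In all other cells Lpl was 7.39-fold lower in Acomys, Hmgcs1 20.7-fold lower and Cd36 3.12-fold higher. The naming markers Scd1, a desaturase (1.10 against 4104 CPM), and Elovl6, an elongase (22.0 against 2631 CPM), were lower, and the marker Plin2, of lipid droplets (1879 against 803 CPM), was higher. Scd2 was 4.25-fold higher (3.27 to 5.57). Fa2h, named as lower, led the Mus cluster of mature sebocytes and is not read as a result. Fbp1, Cyp1a1, Mrpl53 and Atp6v0c were higher and Cebpa lower, each within 4-fold of its ratio elsewhere, and Ptgds, without a UMI in the Mus class, was at least 115-fold higher, against 219-fold elsewhere. The raw lipid median lay at -0.64 where the median of all genes of the class was -0.62, and without the naming markers it was at percentile 10.9. Relative to all other cells it was -0.87 (percentile 0). Without cycling clusters the raw median was -1.89 and the relative median -1.92, each at percentile 0.

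Of 18 lists compared in sebocyte-like cells, 5 lay outside the random lists, the lipid list among them. Proliferation genes had a median of -1.78 (percentile 0.4), with 10 of 15 members at least 2-fold lower in Acomys and none higher. Mki67 was 9.30-fold lower (6.12 to 14.7) and Top2a, a topoisomerase, 7.85-fold (5.73 to 11.0). A cycling cluster held 183 of the 271 Mus cells. Without cycling clusters the proliferation median was 1.59, the opposite sign. The Mus cells left were the 88 mature ones, whereas 39 Acomys cells (11.9% of the class) were mature, so that value compares unlike mixes of cells. Antioxidant genes had a median of 1.08 (percentile 100) and a mean of -0.05, with 10 of 18 members at least 2-fold higher and 4 lower. Prdx6, a peroxiredoxin, was 2.90-fold higher (2.71 to 3.11) and Txn1, a thioredoxin, 2.86-fold (2.72 to 3.02), whereas Cat, catalase, was 15.9-fold lower (11.8 to 21.8) and the metallothionein Mt2 48.9-fold (37.9 to 64.2). The chemokine list had a median of 2.73 (percentile 99.96), with 3 of 5 members at least 2-fold higher and 2 lower. Ccl20 was 10.6-fold higher (6.78 to 17.3) and Cxcl16 6.66-fold (5.12 to 8.77), while Cxcl12 was 11.7-fold lower (3.74 to 58.7). Epidermal barrier genes had a median of 0.93 (percentile 99.91), with 6 of 12 members at least 2-fold higher and 2 lower. Krt1 was 3.08-fold higher (2.70 to 3.52) and Lor 8.23-fold lower (6.75 to 10.1). Relative to all other cells the chemokine and barrier medians were -0.44 (percentile 24.2) and -0.16 (48.8), the opposite sign, and the antioxidant median was 0.053 (87.6), all inside the random lists. Without cycling clusters the relative antioxidant median was 0.72 (percentile 99.99), outside the random lists, and the relative barrier median -0.12 (42.9), inside them. These values also compare the unlike mixes of mature and other cells. With free RNA subtracted the chemokine median was 0.36.

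The share of basal cells with a UMI of a cell cycle gene was compared after thinning each cell to 2000 UMIs of shared genes, which left out 2 Mus and 6 Acomys cells. Mki67 was found in 8.90% of Mus (7.96 to 9.91) and 14.3% of Acomys basal cells (12.1 to 16.8), and Birc5 in 12.8% (11.7 to 14.02) and 27.2% (24.3 to 30.2). Top2a was found in 11.96% (10.9 to 13.1) and 16.3% (13.96 to 18.9), and Ube2c in 11.8% (10.7 to 12.9) and 19.1% (16.6 to 21.8). Unthinned shares were 18.1% and 26.7% for Mki67, 19.5% and 25.1% for Top2a, 23.4% and 39.0% for Birc5, and 21.1% and 30.4% for Ube2c. Their CPM lay in the same order, at 98.9 and 139 for Mki67, 173 and 188 for Top2a, 200 and 317 for Birc5, and 242 and 305 for Ube2c. Suprabasal cells, which have left the cell cycle, gave background shares of 1.78% and 0.828% for Mki67, 1.96% and 1.14% for Top2a, 3.25% and 3.21% for Birc5, and 3.68% and 3.73% for Ube2c. Median shared UMIs were 6712 in Mus and 5658 in Acomys basal cells, and 11808 and 7707 in suprabasal cells. With the unnamed clusters of basal markers counted in, the shares were 10.0% in Mus (9.07 to 11.05) and 9.18% in Acomys (7.81 to 10.7) for Mki67, 12.4% (11.3 to 13.5) and 10.4% (8.91 to 11.9) for Top2a, 12.5% (11.5 to 13.6) and 12.2% (10.6 to 13.8) for Ube2c, and 15.6% (14.4 to 16.8) and 17.7% (15.9 to 19.7) for Birc5. The intervals overlapped for all 4 genes, so no order is read from them.

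Ratios between classes of the same library, in which the reference annotation is shared, were set beside each other in the species; this comparison was added after the data were examined, and the classes were named with the same markers in each library. Across 2786 genes, the log2 ratio of suprabasal to basal CPM in Mus correlated with that in Acomys at Pearson's r = 0.819 and Spearman's rho = 0.733. Of 78 genes at least 4-fold higher in Mus suprabasal cells, 74 were higher in Acomys too, and 131 of 131 genes at least 4-fold lower were lower. Of those at least 4-fold apart in Acomys, 63 of 63 were higher and 130 of 136 lower in Mus. Sult2b1, a cholesterol sulfotransferase, was higher in suprabasal cells by log2 3.80 in Mus and 3.43 in Acomys, and Hmmr lower by -4.49 and -5.54. Endou, Crabp2 and Top2a led clusters of these classes and are not read as results. The barrier list, which holds naming markers, had a median of 3.42 in Mus and 1.56 in Acomys, the proliferation list -3.46 and -4.50, and the matricellular list -2.69 and -2.68. Other lists lay on opposite sides of 0, with no test of the difference. A median covers the members of at least 10 CPM in that library, so the genes can differ between the libraries. Antioxidant genes had medians of 0.12 (percentile 98.9, 18 members) in Mus and -0.63 (1.42, 16 members) in Acomys. Immediate early genes had 0.21 (99.5, 15 members) and -0.46 (19.2, 14 members), and p53 and arrest genes 0.075 (98.7, 13 members) and -0.86 (4.61, 8 members). The Acomys medians of immediate early and p53 genes lay inside the random lists. Unnamed clusters were not counted in here. Sebocyte-like to basal ratios correlated less, at r = 0.626 and rho = 0.552 across 2887 genes. Of genes at least 4-fold apart in Mus, 101 of 112 were higher and 57 of 64 lower in Acomys; of those in Acomys, 66 of 66 were higher and 62 of 91 lower in Mus. The lipid list had medians of 3.39 (18 members) and 1.62 (14 members). The proliferation list, with most Mus sebocyte-like cells in a cycling cluster, had 0.30 (94.9) and -2.76 (0), and the lysosome list -0.32 (1.61) and 0.44 (99.1). Hair follicle and appendage-like to basal ratios correlated at r = 0.697 and rho = 0.537 across 2893 genes, where clusters with other leading genes make up the class in each library.

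**Figure D3:**
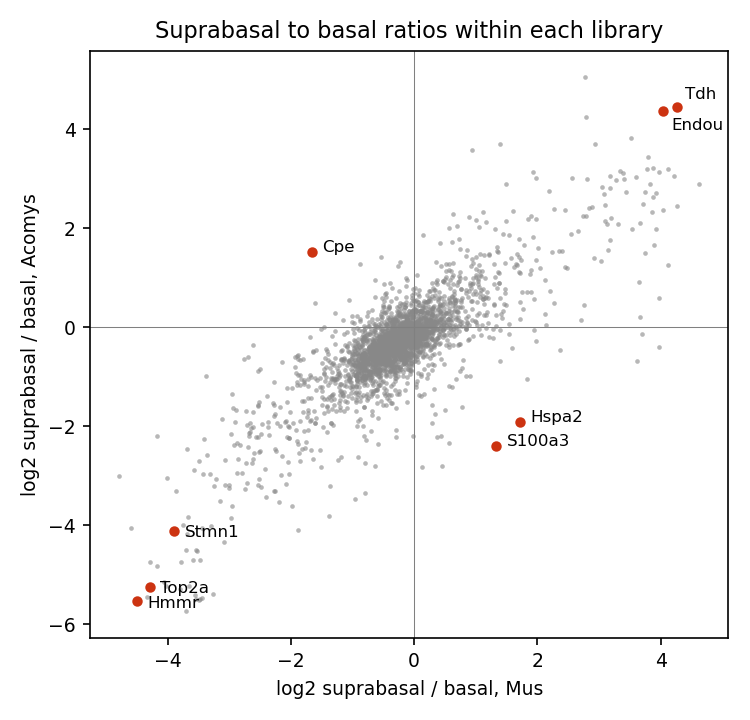
Log2 ratio of suprabasal to basal CPM per gene in Mus (x axis) and in Acomys (y axis), with grey points for 2786 genes and red points for named examples. Endou, at 4.04 and 4.37, and Top2a, at -4.29 and -5.24, are leading genes of clusters of these classes, whereas Cpe, Hspa2 and S100a3 lie on opposite sides of 0.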

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

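The tests of unnamed clusters, of the UMI minimum by itself, of free RNA, of the Scd genes and of genes with an identifier in place of a symbol were chosen after the result they measure was seen.

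For 14 genes the ratio of a class to basal cells went opposite ways in the species, by at least 2-fold on both sides; the difference between the species was not tested. The log2 ratio of suprabasal to basal CPM was -1.66 in Mus and 1.53 in Acomys for Cpe, 1.71 and -1.91 for Hspa2, and 1.33 and -2.39 for S100a3. The sebocyte-like to basal ratio was -2.0005 and 1.87 for Ctsl, 2.25 and -2.29 for Fam3c, 2.89 and -1.29 for Fst, -1.74 and 1.44 for Hpgd, 3.03 and -2.45 for Irx4, 2.22 and -1.93 for Ncoa7, and -4.05 and 1.97 for Sectm1a. The hair follicle and appendage-like to basal ratio was 1.85 and -1.58 for Abhd12b, -1.88 and 1.40 for Cyr61, 1.42 and -1.58 for Dcn, and -1.42 and 4.03 for Il34. Ncoa7 led an Acomys basal cluster, and Cyr61 and Il34 led Acomys follicle clusters. Outside the comparisons, 32.1% of the UMIs of Acomys cells lay on 8324 genes whose name is an identifier alone.

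The basal keratinocyte-like share was 51.8% in Mus and 19.7% in Acomys. Clusters with basal markers that stayed unnamed did not account for all of it: with them counted in, the Acomys share minus the Mus share was -20.3 percentage points (-22.1 to -18.4), and -11.9 (-13.5 to -10.3) with a minimum of 1000 UMIs as well. The UMI minimum by itself stays open, since the difference was -17.1 points at 1000 UMIs and 5.25, the opposite sign, at 500 UMIs. With the unnamed clusters counted in at 500 UMIs it was -10.9 (-12.0 to -9.78), so the opposite sign depended on clusters left unnamed. A species difference in the makeup of the ear epidermis may add to the share difference and stays open as untested. Differences in how cells were released from each ear stay open too.

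In each of the 4 epithelial classes, 39 genes differed over 50-fold between the libraries. All were picked at 30 CPM or more in each class of the higher library. Free RNA in the droplets is argued against as the source: the median level of these genes in the classes was 92.5% (quartiles 82.0 to 107.96) of their level in barcodes with 1 to 10 UMIs, where a source in free RNA alone needed under 20%; the lowest were Krt25 at 31.9% and Mmp3 at 40.0%. Annotation and read capture that differ between the references could produce such ratios and stay open. The test on ribosomal protein genes decides nothing: 3.23% of them lay over 4-fold from the family's median ratio, but this was 1 of 31 genes, Rpl7l1, which is not a part of the particle, and so small a family meets the lower bound of 1% only with 0 genes. A species difference in expression stays open as untested.

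Lipid metabolism genes were lower in Acomys sebocyte-like cells relative to the other cells (median log2 -0.87), a pattern that hardly showed in the raw median. A smaller share of mature sebocytes stays open as a cause. In the mature clusters alone (88 Mus and 39 Acomys cells, 32.5% and 11.9% of the class) the relative median was -1.07, at percentile 0 of random lists. That met the limit set against this cause. The raw median, however, was -0.35 at percentile 4.4, inside the random lists, with 7 of 18 members at least 2-fold lower and 2 higher. The clusters were picked by sebocyte markers that include members of the lipid list. The other cells also hold the remaining sebocyte-like cells, so the relative median depends on those too. Scd1 reads counted under Scd2 or Scd3 are argued against, since the summed level of the Scd genes was 29.96-fold lower in Acomys (26.4 to 34.1). The sum cannot decide on reads dropped because they match more than 1 Scd gene, since these would lower it too. Acomys reads of lipid genes may instead lie under genes with an identifier alone, and what this needs is present but thin: 1 such gene (ACOCA10068_EIv1_0056740, 1347 CPM and 10.4-fold over the other cells) passed both limits in the mature cluster, and what it encodes is not given in the sources used here. A species difference in sebum synthesis stays open as untested.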

How the results depend on the processing

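No paired analysis was possible because each species has 1 library. Alternatives added after the data were examined are those that count unnamed clusters in, leave out cycling clusters or leave out naming markers. Of 1432 alternative values of the 202 named gene ratios, 1047 stayed within the counting interval of the main value, 331 moved with the same sign and 54 reversed (a ratio whose interval held 1 was not counted as reversed); of 167 for the 26 list medians, 113, 44 and 10; of 40 for the 4 class shares, 20, 16 and 4; of 16 for the 8 UMI shares, 2, 14 and 0; of 6 for the marker sums, 1, 5 and 0. Lifting the mitochondrial limit left the 4 class shares within their intervals. None of the 168 gene ratios run without doublet removal or with cells weighted equally reversed. The scalings move every gene of a class by the same amount, too little to turn a large ratio. Centring made each log2 ratio lower by 0.119 in basal, 0.152 in follicle and 0.135 in endothelium-like cells, and leaving out ribosomal proteins subtracted -0.103 from each in sebocyte-like cells, which made it higher, so ratios are read relative to the other genes. Endothelium Cxcl14, at 0.013 with an interval that held 0, was -0.12 when centred. Depth limits the genes: with 271 sebocyte-like and 366 follicle cells in Mus, few UMIs set the upper bound of many ratios. Except where a value's own construction shows it (fewer cells, genes or list members), the cause was not tested.

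Class shares are Acomys minus Mus in percentage points. A minimum of 500 UMIs gave 5.25 (reversed) for basal, -32.04 for suprabasal, 0.483 for follicle and 1.82 for sebocyte cells; a minimum of 1000 UMIs gave -17.1 for basal, 5.26 for follicle and 1.88 for sebocyte cells. A mitochondrial limit of 10% gave -28.4 for basal and -0.705 for suprabasal cells. Cluster resolution 0.5 gave 0.512 (reversed) for suprabasal and 0.841 for follicle cells, and resolution 2.0 gave -25.3 for basal and -1.67 (reversed) for follicle cells. Using 15 components gave -21.5 for basal and 1.36 for follicle cells. Joint clustering gave -22.3 for basal and 0.640 (reversed) for suprabasal cells. Each joint cluster of these classes held nearly 1 library alone, so the species were hardly placed in common clusters. Counting unnamed clusters in gave -20.3 and -0.733, and keeping doublets gave 10.3 for follicle cells.

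List medians are log2 ratios. Counting unnamed clusters in gave 3.84 for basal chemokine, 0.43 for basal barrier, -2.32 for suprabasal protease, 0.62 (reversed) for suprabasal barrier and 1.86 for endothelium interferon genes. Subtracting free RNA gave 2.195 for chemokine and 0.91 for barrier genes in basal cells, 1.66 for suprabasal interferon genes, -2.72 for protease and 0.16 for chemokine genes in follicle cells, and 0.36 for chemokine, -2.18 for proliferation and 1.22 for barrier genes in sebocyte cells. Members of at least 1 UMI gave 1.61 for basal chemokine, -0.45 (reversed) for basal interferon, 0.18 (reversed) for suprabasal protease, 0.66 for suprabasal interferon, 0.56 (reversed) for follicle protease and -0.58 for sebocyte lipid genes. Members of at least 50 CPM gave 0.91 for basal barrier, 1.72 for suprabasal interferon, 1.15 for sebocyte barrier and 2.11 for endothelium interferon genes. Without cycling clusters the basal medians were 3.41 for chemokine, 0.95 for interferon and 0.54 for barrier genes. The sebocyte medians without them were 1.59 (reversed) for proliferation and -1.89 for lipid genes, with unlike shares of mature cells in the libraries. Centring gave 0.47 for basal barrier genes, leaving out ribosomal proteins -0.54 for sebocyte lipid genes, and leaving out naming markers -1.49 for suprabasal barrier and -0.58 for sebocyte lipid genes. Relative to the ratio in all other cells, basal medians were 0.065 for chemokine, 0.19 for interferon and 0.30 for barrier genes; suprabasal ones -0.45 for protease, 0.35 for chemokine, 0.56 for interferon and -2.60 for barrier genes; follicle ones -0.18 for protease and -0.64 (reversed) for chemokine genes; sebocyte ones -0.44 (reversed) for chemokine, 0.053 for antioxidant, -0.16 (reversed) for barrier and -0.87 for lipid genes; endothelium ones 0.87 for chemokine, 0.24 for interferon and 0.35 for barrier genes; chondrocyte-like ones -1.23 (reversed) for papillary and 1.22 for reticular fibroblast, 0.40 for interferon, 0.24 for barrier and 0.22 (reversed) for epithelial adhesion genes. Members of at least 50 CPM gave -0.20 for epithelial adhesion genes in chondrocyte-like cells.

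Gene ratios (log2) reversed mostly relative to the ratio in all other cells, where a gene that differs alike everywhere lies near 0. In basal cells these were Mrpl53 -0.45, Atp6v0c -0.43, Emp1 0.39, Elof1 0.72, Mmp3 1.51, Smim10l1 0.74, Ccl20 -0.9997, Psmb9 -0.99, Krt1 -0.018 and Lor 0.46. In suprabasal cells they were Cyp1a1 -1.10, Ctsl -0.57, Ccl20 -0.99, Cxcl16 -1.01, Krt10 -1.48, Krtdap -0.96 and Tgm3 0.83. In follicle cells they were Atp6v0c -0.025, Cyp1a1 -3.21, St3gal5 -0.47, Emp1 0.60, Eef1d 0.22, Elof1 0.95, Adamts1 0.19, Ctsb -0.031, Ctsl -0.34, Timp3 0.061, Ccl2 -0.99 and Cxcl16 -0.083. In sebocyte cells they were Cyp1a1 -1.47, Mrpl53 -0.44, Atp6v0c -0.49, Ccl20 -0.44, Gsr 0.075, Txn1 -0.36, Krt10 -0.14, Krtdap -0.099 and Fabp4 -0.091. In endothelium cells they were Atp6v0c -0.84, Nme2 -0.084, Ccl7 -0.35, Ifitm3 -3.08, Krt1 -0.98, Lor 0.31, Apoe -0.12, Fabp4 -1.56, Fabp5 -0.94, Hmgcs1 0.80 and Scd1 1.49. A minimum of 1000 UMIs reversed suprabasal Cxcl14 (-0.048) and Klk7 (0.74), counting unnamed clusters in reversed suprabasal Klk7 (0.62), and subtracting free RNA reversed follicle Ccl2 (-0.60) and endothelium Ccl8 (-0.26).

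Unthinned shares of basal cells with a UMI, in Mus and Acomys, were 18.1% and 26.7% for Mki67, 19.5% and 25.1% for Top2a, 23.4% and 39.0% for Birc5, and 21.1% and 30.4% for Ube2c. With unnamed clusters counted in, the Mus shares were 10.0% for Mki67 and 15.6% for Birc5, and the Acomys shares 9.18% for Mki67, 10.4% for Top2a, 17.7% for Birc5 and 12.2% for Ube2c. Over all barcodes the Acomys to Mus ratio of marker sums was 1.92 for fibroblast, 1.35 for endothelium, 5.27 for melanocyte, 1.38 for macrophage and 0.835 for T cell markers.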

Other observations

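Blood endothelium-like cells numbered 149 in Mus and 304 in Acomys with a minimum of 1000 UMIs, a setting chosen for this class after the data were examined because the main cells held 43 and 84. In these cells Ifi27, an interferon-induced gene, was 15.5-fold higher in Acomys (12.5 to 19.5) against 1.25-fold in all other cells, and Psmb9, an immunoproteasome subunit, 11.1-fold (7.96 to 15.8) against 1.84-fold. Isg15, a ubiquitin-like modifier, was 4.05-fold higher (2.26 to 7.80) where it was 1.67-fold lower elsewhere. The interferon response list had a median log2 ratio of 1.37 (percentile 100 of random lists), with 7 of 12 members at least 2-fold higher and 2 lower. Relative to the ratio in all other cells its median was 0.24 (percentile 82.1), inside the random lists, but 1.36 (percentile 100) with unnamed clusters of endothelium markers counted in, outside them. Cd36, a fatty acid transporter, was at 289 CPM in Acomys and 32.5 CPM in Mus, 8.89-fold higher (4.92 to 17.7), whereas in all other cells it was 4.27-fold lower. The lipid metabolism list had a median of 0.63 (percentile 99.39) and a mean of -0.07, with 6 of 18 members at least 2-fold higher and 5 lower; its relative median was 0.41 (percentile 96.99), and 0.46 (98.3) with those clusters counted in.

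Tspan8, a tetraspanin, was 193-fold higher in Acomys endothelium-like cells (53.01 to 1595) against 6.06-fold elsewhere, and Efemp1, a fibulin of the matrix, 159-fold (28.2 to 6322) against 3.37-fold. Atp6v0c and Nme2 were also higher, each near its ratio elsewhere or below it, and St3gal5, without a UMI in the Mus class, was at least 44.2-fold higher, against 216-fold elsewhere. Cav1, the coat protein of caveolae, and Stmn2 had no UMI in the Acomys class and were at least 97.2-fold and 67.6-fold lower, against 36.2-fold and 2.92-fold elsewhere. Il6st, the shared receptor of interleukin 6 cytokines, was 120.2-fold lower (54.9 to 329) against 24.95-fold, and Emp1 was lower as in the other classes. Aqp1, named as lower, led the Mus endothelium cluster and is not read as a result. The chemokine list had a median of 2.37 (percentile 100), with 6 of 8 members at least 2-fold higher and none lower; with genes without a UMI in a library at their bound it was 2.06. Its relative median was 0.87 (percentile 98.4), and 0.65 (95.6), inside the random lists, with the unnamed clusters counted in. Cxcl16 was 6.88-fold higher (4.08 to 12.4). The epidermal barrier list had a median of 1.01 (percentile 99.79), with 6 of 12 members at least 2-fold higher and 1 lower, among them the keratinocyte gene Krt10 at 2.31-fold (2.18 to 2.44); relative to all other cells the barrier median was 0.35 (percentile 91.6), and 0.42 (94.7) with the unnamed clusters counted in, both inside the random lists. Of 24 lists compared, 4 lay outside the random lists.

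Chondrocyte-like cells, which resemble ear cartilage, numbered 55 in Mus and 175 in Acomys with the same minimum of 1000 UMIs, so only list medians were taken. Each library gave 1 such cluster, led by Wif1, Chad and Cytl1 in Mus and by Cytl1, Col1a2 and Comp in Acomys, where Dcn and Ccdc80 were also leading genes and fibroblast cells may be mixed in. Of 29 lists compared, 8 lay outside the random lists. Myofibroblast and contractile genes had a median log2 ratio of 2.42 (percentile 100), with 6 of 8 members at least 2-fold higher in Acomys and none lower, and 2.57 relative to all other cells (percentile 100). Lipid metabolism genes had a median of 0.94 (percentile 99.5), with 9 of 18 members higher and 4 lower, and the reticular fibroblast list 1.46 (percentile 99.1), with 3 of 6 higher and 1 lower; relative to all other cells both stayed outside the random lists, at 0.68 and 1.22. Proliferation genes had a median of 1.14 (percentile 98.5), interferon response genes 1.67 (percentile 99.8) and barrier genes 1.03 (percentile 99.3), and relative to all other cells they lay inside the random lists, at percentiles 93.4, 77.1 and 71.2. The papillary fibroblast list, at 1.63 (percentile 99.3), and epithelial adhesion genes, at -1.11 (percentile 2.03), took the opposite sign relative to all other cells, at -1.23 and 0.22. Genes without a UMI in a library weighed on these medians: with such genes at their bound, the proliferation median was 0.057, the papillary 0.25, the myofibroblast 1.53, the barrier 0.65, the lipid 0.69, the interferon 1.26, the reticular 1.34 and the adhesion median -0.82.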
